A study of Homo sapiens with 4 samples.

How the data were processed

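Gene expression was measured in place on 10x Visium arrays in 4 sections of human psoriatic skin, 1 section per group. The groups were lesional and non-lesional skin before treatment, and lesional and non-lesional skin after treatment. For both post-treatment sections the labels name secukinumab, an antibody that neutralises interleukin-17A. Per the labels' protocols, the skin came from punch biopsies of 3 to 4 mm, was frozen in OCT medium and was sliced into cryosections of 10 µm. The labels do not state whether the sections come from the same person or from different people.

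The deposited values are counts of unique molecular identifiers (UMIs) per gene and spot, made with Space Ranger 1.2.1 per the file headers and without normalization. Genome build hg38 is named in the submitters' processing notes. Each section's table held 36601 genes, of which 36366 identifiers were found in the reference gene table. The 10 symbols that the files give to 2 identifiers were kept apart by identifier. A separate deposited table marks which of the 4992 array spots lie over tissue and where each spot sits, and all spots with counts were over tissue. The images' scale factors were not used here.

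From these counts, each spot over tissue with at least 100 UMIs and at least 3 UMIs of 7 region genes was assigned to a region. A spot was keratin-rich when the UMIs of KRT5, KRT14, KRT1 and KRT10 were at least 50% of the UMIs of those genes plus COL1A1, COL1A2 and COL3A1, and other when they were below 50%. The region genes were not compared between sections, except that collagen CPM is given as a measure of dermal RNA, chosen after the data were seen. UMIs were summed over the keratin-rich spots of each section and divided by that sum's total and scaled to give CPM, the usual rate of counts. A spot covers several cells, so the regions are not cell types.

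The 4 comparisons were lesional over non-lesional before treatment, lesional after over before treatment, lesional over non-lesional after treatment, and non-lesional after over before treatment. With 1 section per group no test was made and no p-value is given. Each gene has the log2 ratio of its CPM with an exact conditional binomial (Clopper-Pearson) 95% interval, CPM values have exact Poisson intervals, and shares of spots have exact Clopper-Pearson intervals. All these intervals cover counting error only. Where a gene had 0 UMIs in a sum, the ratio was computed against a floor of 3 UMIs per sum and is given as a bound.

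The gene lists were fixed before the data were examined, as were the regions, the comparisons, the named-gene rule and all alternatives but those said to have been chosen after seeing the data. The 12 pathway and quality lists were IL-17 response, hyperproliferative keratins and early cornified envelope, late cornification, glycolysis, glucose and lactate transport, HIF-1 targets outside glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, immediate early and heat shock, proliferation, interferon response, and type 17 cytokines and receptors. The 16 marker lists were T cell, dendritic cell, macrophage, neutrophil, mast cell, B and plasma cell, blood endothelium, lymphatic endothelium, fibroblast, pericyte and smooth muscle, melanocyte, sweat gland, hair follicle, sebaceous gland, adipocyte and red blood cell. LORICRIN of the late cornification list was absent from the files, which use the older symbol LOR. Each list is described by the median log2 ratio of its members with at least 10 UMIs over the 2 sums, with a prior count of 0.5, a 95% interval from 1000 Poisson redraws of the counts, and its percentile among 10000 random lists of the same size matched on mean expression within a window of 100 genes, for lists with at least 3 such members. The percentile describes these sections and is not a test. A median with members at 0 UMIs set to their bound is given where such members matter.

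Named genes were taken by rule. In each comparison the genes with at least 50 UMIs over the 2 sums were ranked by the 95% bound of the log2 ratio nearest to 0, and the 12 highest and 12 lowest are named. In the other spots the 6 highest and the 6 lowest are named. The region genes, mitochondrially encoded genes, ribosomal protein genes and sex-linked genes were left out of the ranking. Members of a fixed list are named beside these as examples of the list, by most UMIs or by largest ratio. The rule set no number of such examples, and those named rank among the 6 highest of their list by either measure, a number set after the values were seen. RHCG, KRT16, KRT6A and the type 17 genes with fewer than 10 UMIs were named outside the rule after their values were seen.

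List scores were compared across keratin-rich spots within a section by Spearman's rho after thinning each spot to 500 UMIs, beside 1000 random matched lists. Spots are not replicates and no p-value is given. Keratin-rich spots that held, or touched on the hexagonal array, a spot with at least 1 UMI of CD3D, CD3E, CD3G, CD2, TRAC, TRBC1 or TRBC2 were compared with the other keratin-rich spots of that section. The keratin-rich spots of each section were also divided into 4 runs of equal spot number along their main axis, which gives a spread within a section and not between people. Leiden clusters of all spots with at least 100 UMIs were made from 2000 variable genes, 20 principal components, 15 neighbours and resolution 1, without the pathway list genes.

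The comparison steps were tested on simulated Poisson counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of the 2-fold changes, 81% were called the right way for lesional over non-lesional before treatment, among 7065 genes. The share was 81% for lesional after over before treatment, among 6654 genes, 90% for lesional over non-lesional after treatment, among 3163 genes, and 83% for non-lesional after over before treatment, among 3969 genes. Of the 4-fold changes, 100% were called the right way in each comparison except lesional after over before treatment, at 98%. Intervals of unchanged genes held the true value for 96.1%, 96.2%, 95.8% and 96.6% of genes in that order. In simulated sections where 100 abundant genes were raised in 1 section, the median of all other genes, which should be 0, was -3.55 with CPM, -0.08 with TMM and -0.03 with median-of-ratios scaling. That setting was more extreme than the data, where the CPM median of all genes was -0.83 for lesional over non-lesional before treatment. It shows the direction of such a shift, not its size in these sections.

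Alternatives were no minimum or at least 500 UMIs per spot, a keratin share of at least 80%, Leiden clusters as regions, all spots of a section, TMM scaling, median-of-ratios scaling, CPM without mitochondrial, ribosomal and region genes, every spot thinned to 500 UMIs, and gene minimums of 1 and 50 UMIs. Spots with at least 2000 UMIs and a keratin share of at least 95% were added as an alternative chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and the TMM factors came from edgeR 4.0.16 in R 4.3.3.

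The sections held 3485087 UMIs over 230 spots in pre-treatment lesional skin, 818510 over 662 spots in pre-treatment non-lesional skin, 600928 over 378 spots in post-treatment lesional skin and 518806 over 276 spots in post-treatment non-lesional skin. In the same order, the floor of 3 UMIs in the keratin-rich sum corresponded to 0.861, 3.88, 5.57 and 6.11 CPM. The other spots of the pre-treatment lesional section, 1 spot, were left out of the comparisons.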

Results

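The data are UMI counts from 4 Visium sections of human psoriatic skin: lesional and non-lesional skin before treatment, and lesional and non-lesional skin after treatment with secukinumab. There was 1 section per group, so no difference below has a replicate check, and the intervals cover counting error only. The pre-treatment lesional section was the deepest, with 3485087 UMIs and a median of 2515 UMIs per spot. The pre-treatment non-lesional section had 818510 UMIs and a median of 197.5, the post-treatment lesional section 600928 and 314, and the post-treatment non-lesional section 518806 and 261.

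Keratin-rich spots, where epidermal keratin UMIs outnumbered dermal collagen UMIs, made up 228 of the 230 spots with at least 100 UMIs in the pre-treatment lesional section (99.1%, 95% interval 96.9 to 99.9%). They made up 376 of 554 spots in the pre-treatment non-lesional section (67.9%, 63.8 to 71.7%), 224 of 346 in the post-treatment lesional section (64.7%, 59.5 to 69.8%) and 179 of 254 in the post-treatment non-lesional section (70.5%, 64.4 to 76.0%). In the pre-treatment non-lesional section 105 of the 554 spots had too few region UMIs to be assigned, against 1, 1 and 2 in the other sections, so its share cannot be set beside theirs. These are shares of spots and depend on where a biopsy was sectioned. The boundary was gradual: 5, 136, 180 and 99 spots, in the same order, had a keratin share between 30 and 70%. The median keratin-rich spot held 70.5, 5, 11 and 16 keratin UMIs and 1, 1, 5 and 4 collagen UMIs. Most of the signal came from deep spots. Keratin-rich spots with at least 2000 UMIs, numbering 120, 71, 46 and 49, carried 98.0%, 85.0%, 87.7% and 89.6% of the keratin-rich UMIs.

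**Figure D1:**
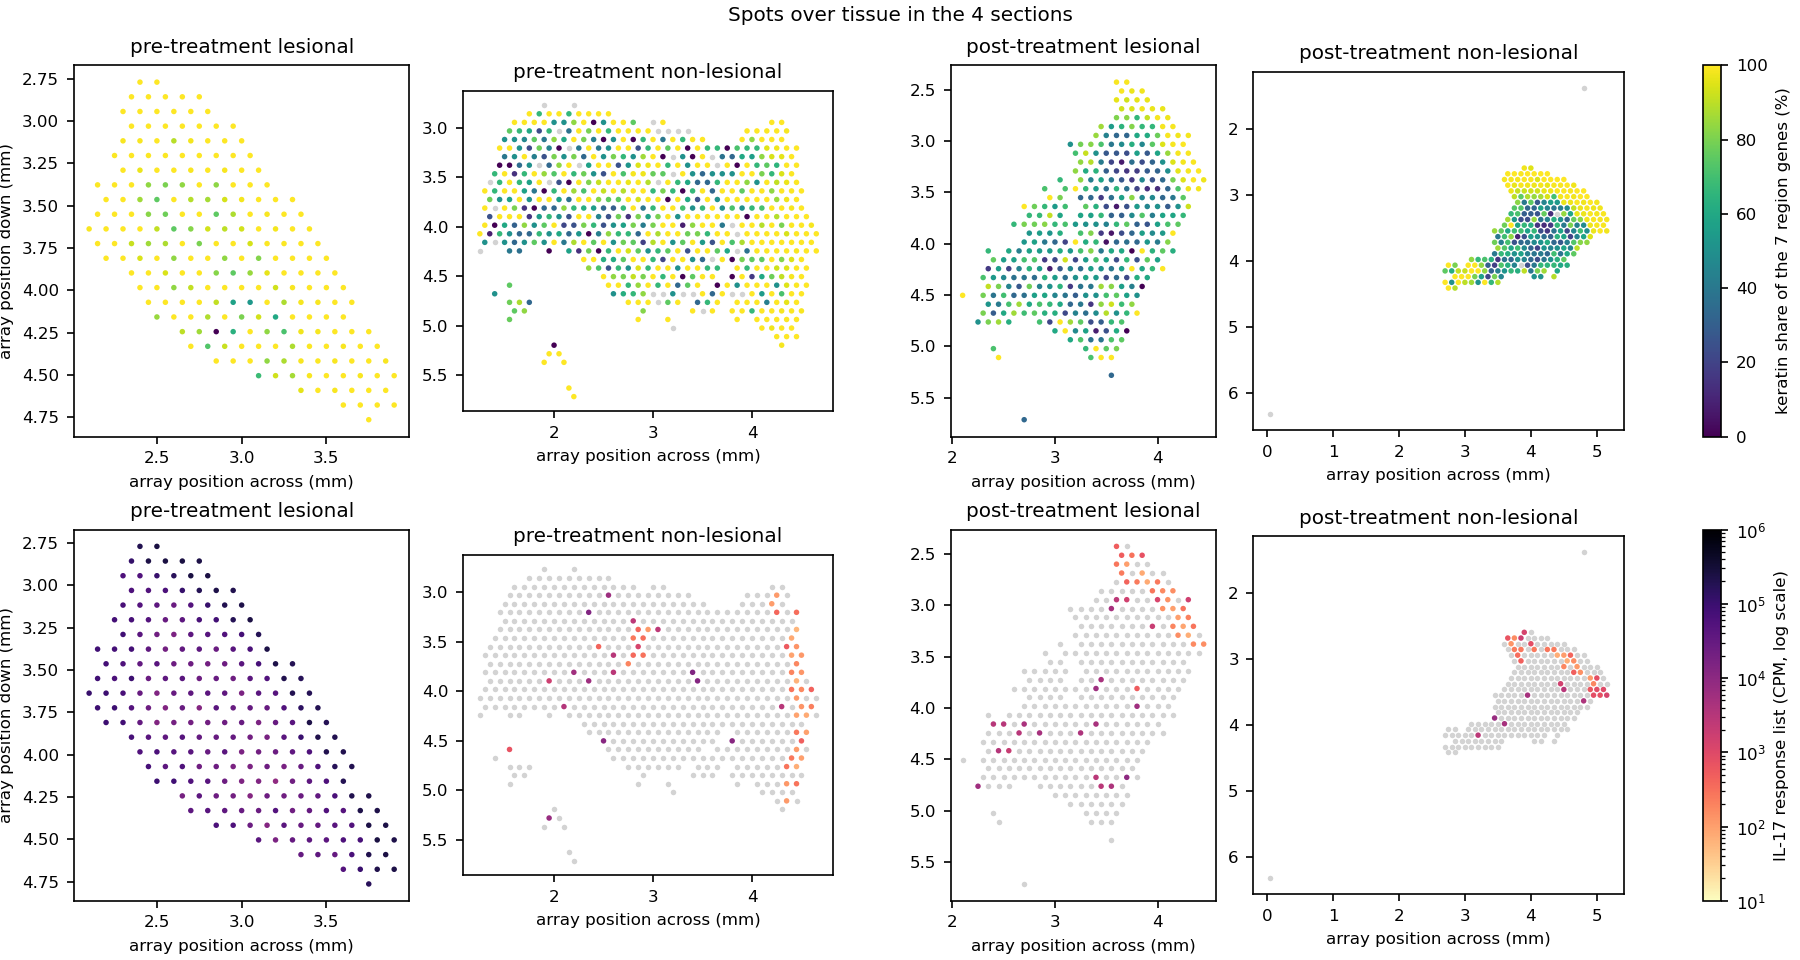
Spots over tissue in the 4 sections by array position in mm, coloured in the upper panels by keratin share of the region genes in percent and in the lower panels by IL-17 response list CPM on a log scale (grey, no value or 0). The keratin-rich sums carried 139750 CPM of that list in the pre-treatment lesional section and 127, 163 and 257 CPM in the pre-treatment non-lesional, post-treatment lesional and post-treatment non-lesional sections.

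Leiden clustering divided the spots into 11 regions, described here by their leading genes. A region led by LCE3A, SPRR1A, DEFB4A and PI3, genes of inflamed outer epidermis, held 53 spots, 52 of them in the pre-treatment lesional section. A region with CXCL10 and LTF among its leading genes, which encode a T cell chemokine and lactotransferrin, held 66 spots, 61 of them in that section. A region led by LCE5A, HLA-DQB2, KRT77 and CD207, the last a Langerhans cell lectin, held 142 spots, 0 of them in the pre-treatment lesional section. The remaining regions were mostly led by stromal, vascular, blood or sweat gland genes, among them a region led by DCD and SCGB2A2 with 101 of its 108 spots in the pre-treatment non-lesional section.

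The first comparison set lesional against non-lesional skin before treatment, the question being what marks the psoriatic plaque. Transcripts that keratinocytes make in response to interleukin-17 dominated the lesional section: S100A7, an antimicrobial protein, had 206355 UMIs against 2 (log2 ratio 14.48, 95% interval 12.63 to 17.53). S100A8 and S100A9, the subunits of calprotectin, had 157990 UMIs against 0, at least 11682-fold higher, and 104329 against 3 (12.91, 11.37 to 15.19). The envelope genes of hyperproliferative epidermis and the interferon response genes were also higher, with list medians of 6.79 and 2.82. Glycolysis genes were not higher: their summed level was 2430 CPM in the lesional and 4606 CPM in the non-lesional section.

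Of 17 measured members of the IL-17 response list, 15 were at least 2-fold higher in the lesional section and 1 was at least 2-fold lower (RHCG, an ammonium transporter, -1.36, -2.17 to -0.51). The list median was 6.11 with the 9 members that had 0 UMIs in 1 sum at their bound, and 9.88 with the prior count (9.77 to 10.18), above all 10000 random lists. PI3, the elastase inhibitor elafin, had 8485 UMIs against 4 (8.88, 7.52 to 10.75). LCN2, the iron-binding lipocalin, and SERPINB3, a protease inhibitor, had 1597 and 2859 UMIs against 0. S100A7 (ENSG00000143556) lies on chromosome 1 of GRCh38 from 153457744 to 153460651, S100A8 (ENSG00000143546) from 153390032 to 153422583 and S100A9 (ENSG00000163220) from 153357854 to 153361023. S100A7, the SPRR2 and LCE3 genes, DEFB4A and the KRT6 genes have near-identical copies that can share reads, so values for a single copy are uncertain.

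In the list of hyperproliferative keratins and early cornified envelope, 14 of 16 measured genes were at least 2-fold higher in the lesional section (median 6.79, 6.06 to 7.29, or 6.18 with bounds, above all random lists). SPRR2E, a small proline-rich envelope precursor, had 23314 UMIs against 40 (7.01, 6.57 to 7.50), and LCE3D, a late envelope protein, 7481 against 9 (7.53, 6.60 to 8.66). KRT16 and KRT6A, keratins of activated epidermis, differed less, at 1.37 (0.99 to 1.76) and 1.38 (0.97 to 1.82). Late cornification genes went both ways, with 5 of 19 at least 2-fold higher, 2 lower and a median of 0.06 (-0.01 to 0.17, percentile 71.3). CALML5, a calmodulin of differentiating keratinocytes, was higher (2.29, 2.22 to 2.36) and KRT77 was lower (-6.65, -7.67 to -5.79).

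S100A7, S100A8 and S100A9 took 13.5% of the keratin-rich UMIs of the pre-treatment lesional section and 0.000647% of those of the pre-treatment non-lesional section. The median log2 ratio over all 12127 genes was -0.83, and 0.11 with TMM or 0.05 with median-of-ratios scaling, so the remaining lists of this comparison are set against it.

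The glycolysis list had a median of -1.07 (-1.26 to -0.92), which is -0.24 relative to all genes and lay at percentile 3.41 of random lists. Of its 16 measured genes 9 were at least 2-fold lower and 0 higher in the lesional section. The median was -0.11 (-0.29 to 0.04) with TMM and -0.17 (-0.36 to -0.03) with median-of-ratios scaling, which shift all genes alike. PKM and ENO1, pyruvate kinase and enolase, stood at -1.57 (-1.77 to -1.37) and -1.48 (-1.66 to -1.29). GAPDH (ENSG00000111640, chromosome 12, 6534517 to 6538371) stood near the median of all genes, with 3229 UMIs against 1282 (-0.84, -0.93 to -0.75). PGAM1, a phosphoglycerate mutase, stood above the median of all genes (0.11, -0.15 to 0.38).

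Genes of glucose and lactate transport had a median of -0.96 (-1.35 to -0.59, percentile 27.4), near that of all genes. SLC2A1, the glucose transporter GLUT1 (ENSG00000117394, chromosome 1, 42925353 to 42958868), had 672 UMIs against 272, or 193 against 352 CPM (-0.87, -1.07 to -0.66). EMB, a chaperone of lactate transporters, stood at 0.81 (0.39 to 1.25). HIF-1 targets outside glycolysis also lay near all genes, with a median of -0.92 (-1.14 to -0.45) that was 0.04 with TMM scaling and 1.0 in thinned spots. BNIP3, a mitophagy receptor, was higher (1.28, 0.74 to 1.87) and NDRG1, a stress-response gene, stood at -1.82 (-2.11 to -1.54).

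Nuclear and mitochondrial genes of respiration went apart. Nuclear oxidative phosphorylation genes had a median of 0.13 (0.01 to 0.18), within the range of random matched lists (to 0.14), and COX7B, a subunit of cytochrome c oxidase, stood at 1.2 (0.99 to 1.41). In spots thinned to 500 UMIs that list's median was -0.01. Mitochondrially encoded genes were lower in the lesional section, with a median of -2.14 (-2.18 to -2.01, below all random lists) and 11 of 12 at least 2-fold lower. MT-CO3 stood at -1.68 (-1.73 to -1.63) and MT-ND5 at -3.38 (-3.63 to -3.13). They made up 1.05% of the keratin-rich UMIs in the lesional and 3.41% in the non-lesional section.

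Interferon response genes were higher in the lesional section in 18 of 19 measured members by at least 2-fold (median 2.82, 2.49 to 3.51, above all random lists). IFI27, an interferon-induced mitochondrial protein, had 11576 UMIs against 117 (4.46, 4.19 to 4.73), and ISG15, a ubiquitin-like modifier, 482 against 15 (2.83, 2.10 to 3.68). Proliferation genes had a median of -1.26 (-1.48 to -0.91, percentile 10.1). Immediate early and heat shock genes, which respond to handling of tissue, had a median of -0.37 (-0.69 to -0.16), which was 0.58 with TMM, 0.52 with median-of-ratios scaling and 0.08 in thinned spots. Of the type 17 cytokines and receptors, 3 genes reached 10 UMIs (median -1.49, -1.91 to -0.94), and the median was 1.15 with at least 1 UMI per gene, so no direction can be given. IL17A, IL17F, IL22 and IL12B had 0 UMIs in all 4 sections, which allows up to 0.861 CPM each in the keratin-rich spots of the pre-treatment lesional section. IL26, a cytokine of type 17 cells, had 3 UMIs there and 0 in the other sections.

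Markers of other cell types moved with these groups. Stromal and vascular markers were lower in the lesional keratin-rich spots, as the mitochondrially encoded and glycolysis lists were: fibroblast -3.36 (-3.62 to -3.21), pericyte and smooth muscle -3.10, blood endothelium -2.61 and lymphatic endothelium -2.55. Sweat gland genes had a median of -7.56 (-8.87 to -6.97), mast cell genes -3.15, and red blood cell genes -3.67. Hair follicle and adipocyte lists had 2 measured genes each (-2.83 and -2.44), of which 1 in each lay within 2-fold. Dendritic cell markers stood at -1.78 (-2.48 to -1.04) but ranged from -3.69 to 3.17 over runs of spots. Macrophage markers stood at -1.49 (-1.83 to -0.93), but at 0.06 in spots with at least 2000 UMIs and a keratin share of at least 95%. T cell markers stood above all genes at 1.09 (-0.09 to 2.45, percentile 93.7, or 0.43 with bounds), beside the interferon response, while 2 neutrophil genes gave 1.61 with the prior count and -0.48 with bounds. Melanocyte genes stood at -0.61 and sebaceous gland genes at -0.57, above all genes, and these were 0.35 and 0.38 with TMM scaling and 0.29 and 0.32 with median-of-ratios scaling. No B and plasma cell gene reached 10 UMIs.

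The 12 genes ranked highest in this comparison were S100A8, S100A7, S100A9, SPRR2A, SPRR2B, SPRR2D, PI3, SERPINB3, LCE3D, LCN2, SPRR2E and SPRR1A. The 12 ranked lowest were DCD, SCGB2A2, SCGB1D2, SCGB1B2P, PIP, KRT19, GABRP, KRT7, KRT77, LCE5A, PRR4 and SNORC, many of them genes of sweat glands. DCD, the sweat peptide dermcidin, had 0 UMIs against 2145 and SCGB2A2, a secretoglobin, 0 against 1060. In the non-lesional section 17 of 662 spots had at least 10 DCD UMIs, and they held 87.3% of its DCD and 78.1% of the UMIs of SCGB2A2, SCGB1D2, MUCL1, AQP5 and PIP. All 17 were keratin-rich, so the non-lesional sum of this comparison holds sweat gland RNA.

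**Figure D2:**
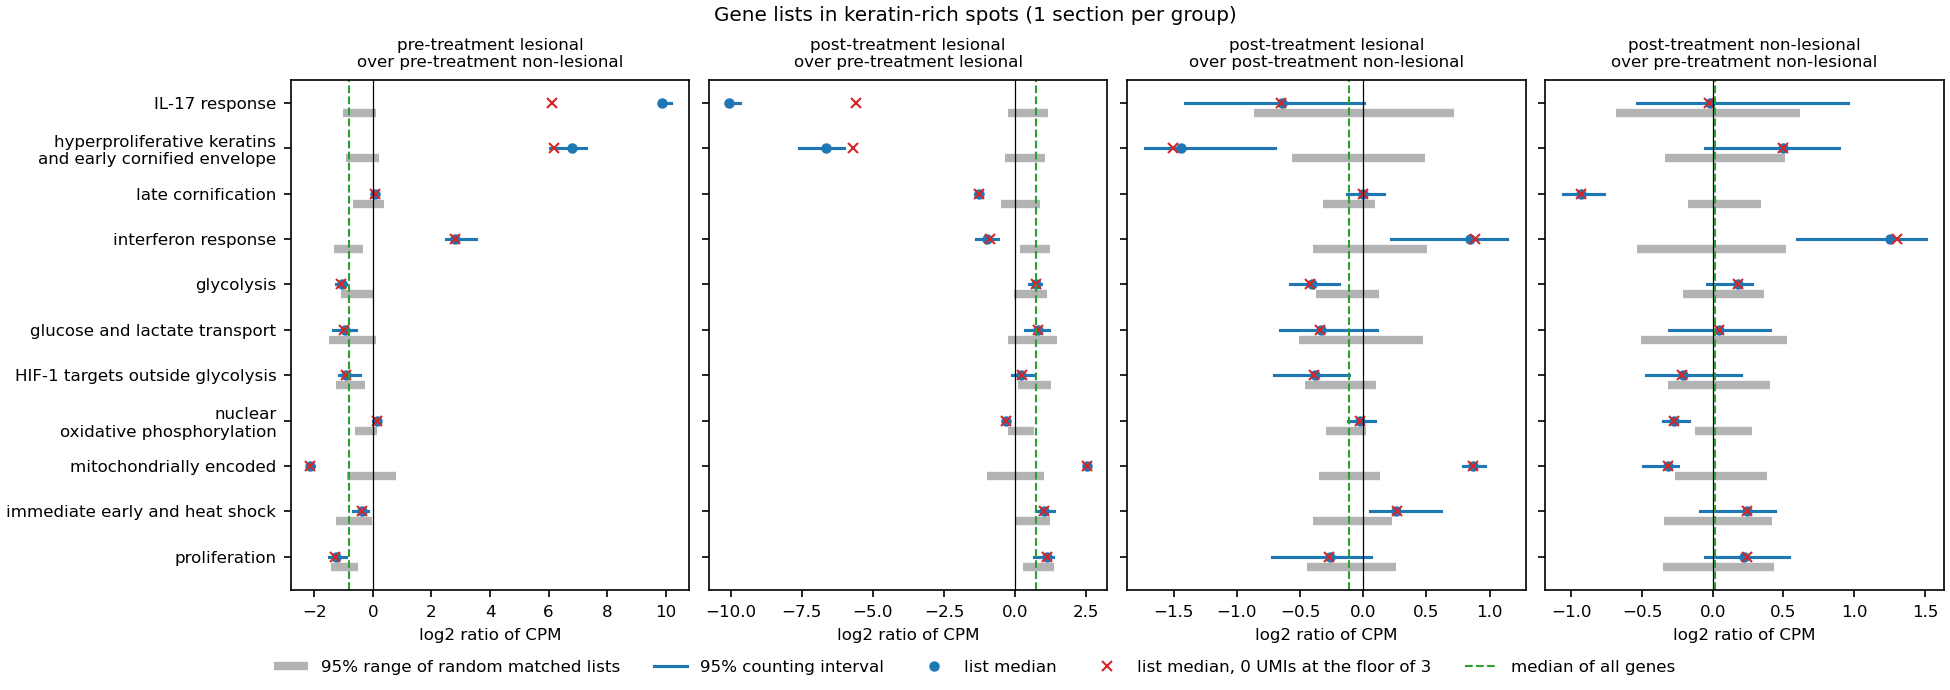
Median log2 ratio of CPM of 11 gene lists in keratin-rich spots for the 4 comparisons (points, with 95% counting intervals; crosses, members with 0 UMIs at the floor of 3; grey bars, 95% range of random matched lists; dashed line, median of all genes). The IL-17 response list stands at 9.88 before treatment and at -0.64 after it, the glycolysis list at -1.07 and -0.40, each lesional over non-lesional.

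The second comparison set lesional skin after treatment against lesional skin before it, the question being what differs after an antibody against interleukin-17A. The IL-17 response list took 163 CPM after and 139750 CPM before treatment, and 16 of 17 measured genes were at least 2-fold lower after treatment. S100A7 had 6 UMIs against 206355 (-12.38, -13.82 to -11.25), S100A8 23 against 157990 (-10.05, -10.71 to -9.47) and PI3 1 against 8485 (-10.36, -15.66 to -7.88). Fibroblast markers were higher after treatment, and CD207, a Langerhans cell lectin, had 44 UMIs against 7 (5.35, 4.18 to 6.74). The median of all 11826 genes was 0.74 and became -0.18 with TMM and -0.11 with median-of-ratios scaling.

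The IL-17 response median was -5.59 with bounds and -10.04 with the prior count (-10.12 to -9.67). Hyperproliferative keratins and early envelope genes were at least 2-fold lower in 15 of 16 members (-6.64, -7.61 to -6.02, or -5.68 with bounds), with SPRR2E at -8.01 (-8.88 to -7.26). Late cornification genes were also lower, by at least 2-fold in 11 of 19 (-1.28, -1.40 to -1.2). CALML5 stood at -2.47 (-2.55 to -2.38), while KRT77 (4.93, 3.98 to 6.02) and KRT2 (1.07, 1.0 to 1.13), keratins of normal upper epidermis, were higher. Interferon response genes had a median of -0.99 (-1.38 to -0.60, below all random lists), and IFI27 stood at -2.62 (-2.79 to -2.45).

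Glycolysis genes had a median of 0.72 (0.49 to 0.91), which is -0.02 relative to all genes and became -0.22 with TMM and -0.15 with median-of-ratios scaling, so no direction can be given. Glucose and lactate transport genes behaved alike, at 0.81 (0.35 to 1.19), -0.12 with TMM and -0.05 with median-of-ratios scaling. Above the median of all genes were ENO1 (1.32, 1.10 to 1.54), PKM (1.27, 1.02 to 1.51) and BSG, the chaperone basigin (1.62, 1.33 to 1.92). GAPDH lay below it (0.43, 0.31 to 0.55). HIF-1 targets stood at 0.22 (-0.11 to 0.62, percentile 5.11) and nuclear oxidative phosphorylation genes at -0.32 (-0.41 to -0.22, percentile 1.29). Mitochondrially encoded genes were higher after treatment in 12 of 12 by at least 2-fold (2.53, 2.41 to 2.61), beside fibroblast (3.56, 3.17 to 4.00) and blood endothelium markers (3.21, 2.72 to 3.64). Within the post-treatment lesional section, though, mitochondrially encoded genes were higher in keratin-rich than in other spots (0.43, 0.37 to 0.50).

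Proliferation genes stood at 1.13 (0.65 to 1.33), immediate early and heat shock genes at 1.01 (0.74 to 1.35) and 3 type 17 genes at 1.01. Dendritic cell markers stood at 3.73 (2.88 to 4.20, above all random lists) but ranged from -3.17 to 4.11 over runs of spots, with FCER1A, a high-affinity IgE receptor subunit, at 50 UMIs against 19 (4.09, 3.30 to 4.93). Mast cell markers stood at 3.37 (2.89 to 4.38) and pericyte and smooth muscle markers at 2.42. Lymphatic endothelium stood at 2.17 and melanocyte at 1.5, but they ranged from -3.67 to 4.13 and from -4.43 to 2.12 over runs of spots. Red blood cell (2.53), macrophage (1.29) and T cell markers (1.23) had no stable direction: red blood cell was -0.85 and macrophage -0.40 in thinned spots, and red blood cell was -1.29 and T cell -0.12 in spots with at least 2000 UMIs and a keratin share of at least 95%. B and plasma cell genes had a median of 7.63 with bounds, and IGKC, the kappa light chain, had 159 UMIs against 1 (10.01, 7.51 to 15.32). The 2 measured sweat gland genes stood at -4.06 with bounds and 3 sebaceous gland genes at -1.03. Hair follicle and adipocyte lists had 1 measured gene each and neutrophils 2, at 0.60, 4.67 and -0.86.

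Ranked highest were IGKC, IGHA1, IGLC2, HLA-DQB2, CCDC80, PI16, FCGBP, CD207, FBLN1, IGFBP5, SPARC and KRT77. SPARC, a matrix protein, had 570 UMIs against 192 (4.26, 4.02 to 4.51). Ranked lowest were S100A7, S100A9, S100A8, SPRR2A, SPRR2B, PI3, SPRR2E, SERPINB3, SPRR2D, LCE3D, LCN2 and DEFB4A. Fibroblast markers took 4169 CPM in the keratin-rich spots after and 366 CPM before treatment. The collagen region genes took 3503 and 106 CPM there, so these spots held more dermal RNA after treatment.

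The third comparison asked how far lesional skin still stood from non-lesional skin after treatment. Epidermal differences were small beside those before treatment. SPRR1B, an early envelope protein, had 86 UMIs in lesional and 257 in non-lesional skin (-1.71, -2.08 to -1.36), and the median of its list was -1.44 (-1.73 to -0.69), with 6 of 10 genes at least 2-fold lower. S100A8 showed no difference beyond its interval (23 against 33 UMIs, -0.65, -1.49 to 0.16), while S100A9 (7 against 30, -2.23, -3.67 to -1.02) and S100A7 (6 against 22, -2.01, -3.60 to -0.66) were lower in lesional skin. Genes of plasma cells, vessels and smooth muscle were higher in lesional skin.

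The IL-17 response list had 5 measured genes and a median of -0.64 (-1.41 to 0.00, percentile 7.61), and late cornification genes stood at 0.00 (-0.13 to 0.17). Glycolysis genes had a median of -0.40 (-0.58 to -0.19), which is -0.29 relative to the median of all genes of -0.11 and lay at percentile 1.04 of random lists. Of its 17 genes 7 had intervals below 0 and 0 above, with PGAM1 (-0.80, -1.16 to -0.44), HK1, a hexokinase (-0.96, -1.45 to -0.48), and ALDOC, an aldolase (-1.02, -1.88 to -0.20), as examples. SLC2A1 had 197 UMIs against 251 (-0.48, -0.76 to -0.21). Transport genes stood at -0.33 (-0.66 to 0.11), HIF-1 targets at -0.38 (-0.71 to -0.12), nuclear oxidative phosphorylation at -0.03 (-0.12 to 0.09) and proliferation at -0.26 (-0.73 to 0.06).

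Mitochondrially encoded genes were higher in lesional skin (0.87, 0.79 to 0.97), with MT-CO3 at 0.98 (0.91 to 1.04). Markers of vessels and stroma were higher with them: pericyte and smooth muscle 2.0 (1.57 to 2.53), blood endothelium 1.70 (1.34 to 2.34), mast cell 1.49 (0.99 to 2.32) and fibroblast 0.97 (0.77 to 1.26). Within the post-treatment lesional section, however, mitochondrially encoded genes were higher in keratin-rich than in other spots, at 48307 against 35814 CPM (0.43, 0.37 to 0.50). In the post-treatment non-lesional section they were lower in keratin-rich spots (-0.27, -0.38 to -0.17). The shared direction thus does not show dermal RNA as the source. Interferon response genes stood at 0.85 (0.22 to 1.14) over 12 measured genes, 2 of them with intervals above 0, and at 0.34 (-0.06 to 0.87) over 20 genes. ISG15 had 41 UMIs against 0. Immediate early and heat shock genes stood at 0.26 (0.06 to 0.61), and FOS, an immediate early transcription factor, at 1.78 (1.2 to 2.40). Melanocyte genes stood at 0.36 (0.04 to 0.68). B and plasma cell genes had a median of 5.84 (4.68 to 7.61), or 6.39 with bounds, but 1 spot held 163 of the 268 UMIs of these genes. They took 2569 CPM, or 631 CPM without that spot, in spots with a keratin share of 50 to 80% and 111 CPM in those with at least 95%. T cell (0.41, -0.59 to 1.35), dendritic cell (-0.06, -0.52 to 0.34), macrophage (0.18, -0.20 to 0.79), red blood cell (-0.09, -0.52 to 0.30) and type 17 genes (0.13, -0.43 to 1.19) showed no difference beyond counting error.

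Ranked highest were IGKC, IGHA1, IGLC2, ACTA2, MYL9, TAGLN, VWF, A2M, ID3, MGP, TPM2 and FOS, mostly genes of plasma cells, vessels and smooth muscle. ACTA2, smooth muscle actin, had 62 UMIs against 10 (2.5, 1.52 to 3.63) and VWF, von Willebrand factor of endothelium, 67 against 13 (2.23, 1.36 to 3.21). MYL9, a myosin light chain, stood at 2.02 (1.37 to 2.73) but at -0.41 in spots with at least 2000 UMIs and a keratin share of at least 95%. Ranked lowest were SYT8, SPRR1B, SPRR2E, SERPINB2, KRT2, FAM83G, PKP1, KLK1, HAGH, C19orf48, CDKN1A and STUB1. PKP1, a desmosome protein, had 784 UMIs against 1438 (-1.01, -1.14 to -0.88) and KRT2 2661 against 4815 (-0.99, -1.06 to -0.92).

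**Figure D3:**
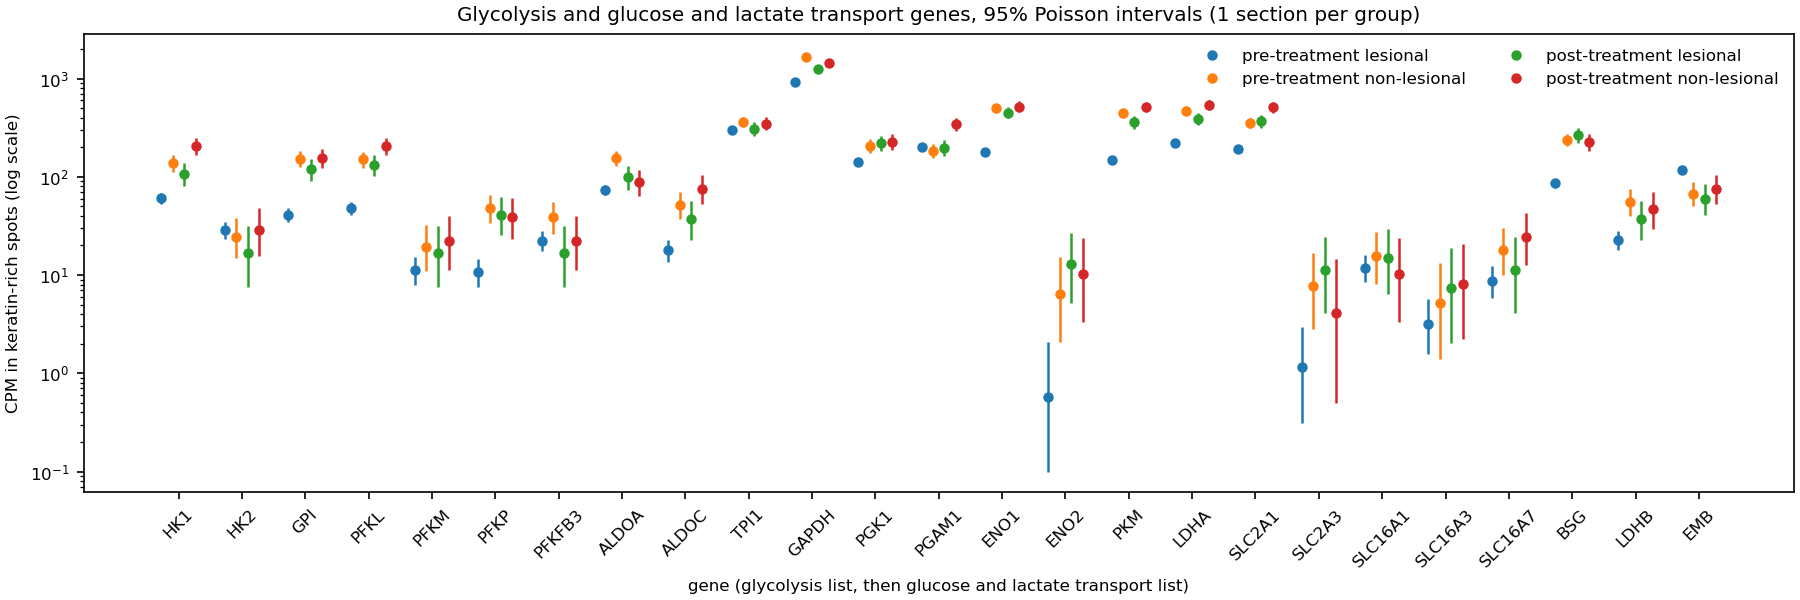
CPM of glycolysis and of glucose and lactate transport genes in the keratin-rich spots of the 4 sections on a log scale, with 95% Poisson intervals. GAPDH had 3229, 1282, 672 and 707 UMIs and SLC2A1 672, 272, 197 and 251 UMIs in the pre-treatment lesional, pre-treatment non-lesional, post-treatment lesional and post-treatment non-lesional sections. These counts are not rates, since the keratin-rich sums held 3484474, 772926, 538746 and 490955 UMIs in that order. As CPM, both genes were lowest in the pre-treatment lesional section.

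The fourth comparison set non-lesional skin after treatment against non-lesional skin before it, which asks what treatment goes with outside the plaque. HLA-DRA and SPRR1B were higher after treatment: HLA-DRA, a class II chain, had 355 UMIs against 170 (1.72, 1.45 to 1.99) and SPRR1B 257 against 38 (3.41, 2.92 to 3.94). Late envelope genes were lower, LCE2C having 37 UMIs against 392 (-2.75, -3.28 to -2.26). Sweat gland genes were at or near 0 after treatment. The median of all 10393 genes was 0.02.

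The IL-17 response list had 7 measured genes and a median of -0.02 (-0.54 to 0.96), yet S100A8 had 33 UMIs against 0, at least 17.3-fold higher, S100A9 30 against 3 (3.98, 2.29 to 6.33) and S100A7 22 against 2 (4.11, 2.09 to 7.25). Hyperproliferative keratins and envelope genes stood at 0.50 (-0.05 to 0.89). Late cornification genes were at least 2-fold lower in 9 of 18 (-0.93, -1.06 to -0.77, below all random lists), with a median of 0.05 in thinned spots, while KRT2 of that list was higher (0.92, 0.86 to 0.98). Interferon response genes were higher (1.25, 0.60 to 1.51), by at least 2-fold in 6 of 10 measured members.

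Glycolysis genes showed no difference beyond counting error (0.18, -0.04 to 0.28, percentile 70.9), and all 17 measured genes lay within 2-fold. Transport genes stood at 0.04 (-0.31 to 0.40), with SLC2A1 at 0.54 (0.29 to 0.79), and HIF-1 targets at -0.21 (-0.47 to 0.20). Nuclear oxidative phosphorylation genes were lower (-0.27, -0.35 to -0.17, percentile 0.05), as were mitochondrially encoded genes (-0.32, -0.49 to -0.25), beside fibroblast markers at -1.14 (-1.32 to -0.84). Proliferation genes stood at 0.22 (-0.06 to 0.54), immediate early and heat shock genes at 0.24 (-0.09 to 0.44) and 3 type 17 genes at -0.59, or 0.35 with at least 1 UMI per gene.

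Dendritic cell markers stood at 1.66 (1.12 to 2.31, above all random lists) but ranged from -3.02 to 3.54 over runs of spots, with CD207 at 46 UMIs against 20 (1.86, 1.07 to 2.69) and CCL19, a chemokine of mature dendritic cells, at 49 against 6 (3.68, 2.46 to 5.20). T cell markers stood at 1.46 (0.22 to 2.25) from 4 measured genes and melanocyte markers at 0.56 (0.21 to 0.98). Pericyte and smooth muscle (-2.41, or -1.74 with bounds), mast cell (-1.66), blood endothelium (-1.19) and red blood cell markers (-1.03) were lower, and macrophage markers stood at -0.51 (-1.08 to 0.03). Lymphatic endothelium markers stood at -1.63 with 1 of 5 intervals below 0, but at 0.71 in thinned spots, 0.60 with at least 50 UMIs per gene and 0.74 in deep spots with a keratin share of at least 95%. Sweat gland genes had a median of -4.85 with bounds, and DCD had 0 UMIs against 2145, at least 454-fold lower.

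Ranked highest were SPRR1B, CCL19, HLA-DQB2, HLA-DPA1, HLA-DQB1, WDR18, HLA-DRA, CALML3, HLA-DPB1, FCGBP, EIF5AL1 and CYP4B1. Of these CALML3, a calmodulin of epithelium, had 342 UMIs against 164 (1.72, 1.44 to 1.99). Reads can be shared among the HLA class II genes. Ranked lowest were DCD, SCGB2A2, MUCL1, SCGB1B2P, SCGB1D2, KRT19, AQP5, S100P, PIP, KRT7, WFDC2 and GABRP.

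The design also allows the lesional over non-lesional ratio after treatment to be set against that before it. For glycolysis the ratio was -1.08 before and -0.40 after treatment, a difference of 0.68 (0.48 to 1.02). The median of all genes moved at least as far, from -0.83 to -0.11, so no shift of glycolysis beyond that of all genes is shown. Random lists of like expression moved less, from -0.52 to -0.13, so the answer depends on the reference. The interferon response difference was -2.5 (-3.24 to -1.87), the mitochondrially encoded difference 3.04 (2.89 to 3.14) and the nuclear oxidative phosphorylation difference -0.15 (-0.25 to 0.02). Random lists matched in expression to the nuclear list had medians of -0.18 before and -0.14 after treatment. These differences have counting intervals only.

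Outside the keratin-rich region, spots were shallow and 1370 and 663 genes were measured. Lesional over non-lesional after treatment, ADIRF, FTL, GSN, VIM, S100A6 and CRIP1 ranked highest, ADIRF having 125 UMIs against 29 (0.93, 0.34 to 1.56). LGALS7B, SFN, KRT2, CALML5, B2M and HLA-B ranked lowest, LGALS7B, a keratinocyte galectin, having 56 against 75 (-1.60, -2.13 to -1.08). Pericyte and smooth muscle genes were higher there too (1.94, 1.22 to 3.39), while fibroblast genes stood at 0.15 (0.00 to 0.34). In non-lesional skin after over before treatment, LGALS7B, KRT2, SPARC, HLA-B, CCDC80 and B2M ranked highest and CCN5, VIM, S100A4, GSN, CLEC3B and FTH1 lowest. SPARC had 264 UMIs against 52 (1.92, 1.48 to 2.38) and VIM, the mesenchymal filament vimentin, 50 against 105 (-1.5, -2.01 to -1.0). Fibroblast genes stood at -0.53 (-0.77 to -0.17).

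Within sections, the ratios are of a list's summed CPM in keratin-rich over other spots, not medians of its members. Fibroblast genes were lower in keratin-rich spots in the 3 sections with other spots. They stood at -3.29 before treatment in non-lesional, -2.97 after treatment in lesional and -3.63 after treatment in non-lesional skin. Melanocyte genes, which belong to the basal epidermis, stood at 1.59 (-0.28 to 4.64), 1.32 (0.52 to 2.25) and 1.48 (0.10 to 3.37). Summed glycolysis genes differed little between regions, at 0.29 (-0.04 to 0.64), 0.03 (-0.18 to 0.23) and 0.07 (-0.20 to 0.35). In the same order, medians of members were 0.84, -0.03 and -0.33 for glycolysis and 4.26, 1.61 and 2.56 for melanocyte genes. The medians of all genes were 3.08, 0.14 and 0.29, above the glycolysis median in each section. In the pre-treatment non-lesional section the other spots held 19644 UMIs against 772926 in keratin-rich spots. A gene with 0 UMIs in those other spots takes a high ratio from the prior count. Medians over genes there thus depend on depth, and a lower glycolysis median does not show depletion.

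The series title raises a link between epithelial metabolism and immunity, so list scores were compared across spots. In the pre-treatment lesional section 170 keratin-rich spots had at least 500 UMIs, and the IL-17 response score had a rho of -0.15 with glycolysis (percentile 35.1 of random lists). The rho was -0.12 with glucose and lactate transport (28.2), -0.00 with HIF-1 targets (80.8) and -0.15 with nuclear oxidative phosphorylation (30.7). All 4 values lay within the range of random matched lists. The median thinned spot held 1, 0, 0 and 5 UMIs of these lists in that order, so these values cannot exclude a relation. With spots thinned to 1000 UMIs the rho with glycolysis was -0.44 (percentile 10, random lists from -0.57 to 0.71). In the other sections 3, 4 and 9 thinned spots held a UMI of the IL-17 response list, too few for a value. The minimum of 10 such spots was chosen after seeing the data.

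T cell UMIs were found in 54 spots of the pre-treatment lesional section and in 19, 21 and 15 spots of the pre-treatment non-lesional, post-treatment lesional and post-treatment non-lesional sections. These sections held 3485087, 818510, 600928 and 518806 UMIs in that order. Such counts of spots rise with depth, so they show no difference in T cells between sections. In the pre-treatment lesional section, glycolysis took 2509 CPM in keratin-rich spots at or next to a T cell UMI and 1883 CPM in the rest (0.41, 0.31 to 0.52). IL-17 response genes stood at -0.41 (-0.42 to -0.40), glucose and lactate transport at 0.07 (-0.15 to 0.29) and HIF-1 targets at -0.20 (-0.37 to -0.03). Glycolysis stood at -0.37 (-0.46 to -0.27), 0.05 (-0.11 to 0.21) and 0.21 (0.08 to 0.34) in the other sections, so its direction was not shared. Spots near a T cell UMI were deeper, with a median of 6985 against 608 UMIs in the pre-treatment lesional section.

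Dividing the keratin-rich spots of a section into 4 runs gave a spread within sections. The IL-17 response median for lesional over non-lesional skin before treatment ranged from 6.86 to 10.09 over runs, the glycolysis median from -2.13 to -0.75 and the mitochondrially encoded median from -3.60 to -1.29. For glycolysis the range was -0.28 to 0.83 for lesional skin after over before treatment, -0.84 to 0.37 for lesional over non-lesional after treatment, and -0.78 to 0.33 for non-lesional after over before treatment. The mitochondrially encoded range was 2.27 to 2.80 for lesional skin after over before treatment, but it held 0 for lesional over non-lesional after treatment (-0.36 to 1.32) and for non-lesional after over before treatment (-1.81 to 0.86). Before treatment, lesional over non-lesional ranges held 0 for late cornification, transport, HIF-1, nuclear oxidative phosphorylation, immediate early, proliferation and type 17 lists. So did those for T cell, dendritic cell, melanocyte, hair follicle, sebaceous gland and adipocyte markers. In lesional skin after over before treatment, they held 0 for transport, HIF-1, immediate early, proliferation, interferon response and type 17 lists. Markers doing so there were T cell, dendritic cell, neutrophil, lymphatic endothelium, melanocyte, hair follicle, sebaceous gland and red blood cell. For lesional over non-lesional after treatment, the range of every list with one held 0 except interferon response, mast cell, and B and plasma cell. For non-lesional after over before treatment, the exceptions were nuclear oxidative phosphorylation, pericyte and smooth muscle, melanocyte, sweat gland and adipocyte. All other lists with a range held 0 there. A member with 0 UMIs in a shallow run takes a strongly signed ratio from the prior count. For HIF-1 targets in lesional skin after over before treatment, the whole median was 0.22 and that of the lowest run -4.71. For lists with few UMIs a range that holds 0 can thus come from run depth. It does not show that direction differed between parts of a section. The smallest run held 31443, 16675, 9301 and 9301 UMIs in these comparisons.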

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

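The tests chosen only after the result was seen were those in spots with at least 2000 UMIs and a keratin share of at least 95%, the readings of the planned scalings, and the tests of B and plasma cell transcripts. Several lists pointed one way in lesional over non-lesional skin before treatment and the opposite way after it, which is what singled them out; with 1 section per group the difference was not tested. Hyperproliferative keratins and early cornified envelope genes stood at 6.79 before (16 genes) and -1.44 after treatment (10 genes), a difference of -8.23; over the same 17 genes it was -7.74 (-8.20 to -6.25). Mitochondrially encoded genes stood at -2.14 and 0.87, a difference of 3.00. Immediate early and heat shock genes stood at -0.37 and 0.26, a difference of 0.63. Mast cell genes stood at -3.15 and 1.49 (4.64), blood endothelium at -2.61 and 1.70 (4.31), fibroblast at -3.36 and 0.97 (4.33), pericyte and smooth muscle at -3.10 and 2.0 (5.10) and melanocyte at -0.61 and 0.36 (0.97). For 2 of these the opposite sign comes from the median of all genes of -0.83 before treatment: relative to all genes, immediate early and heat shock genes stood at 0.45 before and 0.37 after treatment and melanocyte genes at 0.22 and 0.47, so their direction did not differ. Collagen region genes took 106 CPM in lesional and 758 CPM in non-lesional keratin-rich spots before treatment, and 3503 and 2210 CPM after it. The fibroblast, vascular, smooth muscle and mast cell lists thus changed direction as the dermal content of these spots did. A change in those cells cannot be told apart from it.

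Glycolysis genes were lower in the pre-treatment lesional than in the pre-treatment non-lesional keratin-rich spots. If a few genes with very many UMIs pushed all others down, the difference should vanish with scalings that resist them: the median was -0.17 (-0.36 to -0.03) with median-of-ratios and -0.11 (-0.29 to 0.04) with TMM scaling, the latter added after the value of the former, first named alone, was seen. Most of the size thus goes with the scaling, but both scalings move all genes alike, and the part below the median of all genes was -0.24 with CPM and -0.22 with either scaling, so this test cannot tell what that part comes from. RNA of the dermis would act least in deep, nearly pure spots, where the list still stood at -0.15 relative to all genes (-0.43 to -0.01), which argues against dermis as the whole source, though weakly, since the upper end is close to 0; that prediction was written before its value was seen. Lesional state stays open as a biological explanation and was not tested, since 1 section per group confounds it with section and depth.

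Mitochondrially encoded genes were lower in the same comparison. With median-of-ratios scaling the median was -1.24 (-1.28 to -1.11), far from 0, which argues against a few abundant genes as the whole cause. In keratin-rich spots with at least 2000 UMIs and a keratin share of at least 95% it stood at -1.04 relative to all genes (-1.09 to -0.88), which argues against dermal RNA as the whole cause. A difference in RNA quality or tissue handling between sections and a difference in the epidermis itself both stay open and cannot be separated in this design. The non-lesional sum also held the 17 keratin-rich spots with at least 10 DCD UMIs. Neither the glycolysis nor the mitochondrially encoded comparison was repeated without them.

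B and plasma cell transcripts lay in the keratin-rich spots of the post-treatment lesional section, a pattern that replaced a wider one, of plasma cell, vessel and fibroblast markers, after its 2 tests had been seen; those tests could not decide on dermal RNA and nothing is drawn from them. RNA spread from the dermis should be depleted in keratin-rich over other spots like stromal and vascular lists. As log2 ratios of summed CPM, these ran from -2.97 (-3.06 to -2.88) for fibroblast to -0.81 (-1.16 to -0.44) for blood endothelium. The B and plasma cell list stood at -0.11 (-0.64 to 0.47), but at -1.45 (-2.03 to -0.83) without the richest spot, so such spread stays open. Cells at the border of the epidermis should make spots with a keratin share of 50 to 80% richer than those under 50%: the ratio was 2.26 (1.72 to 2.85), but 0.24 (-0.43 to 0.92) without the richest spot, so this stays open too. Both comparisons replaced weaker ones, against fibroblast genes alone and between shares of at least 95% and 50 to 80% (-4.53, -5.04 to -4.06), the latter unable to tell border cells from spread. The richest spot held 163 of the 268 UMIs, so the level of 497 CPM in the keratin-rich spots was 196 CPM without it, and no biological explanation was tested.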

How the results depend on the processing

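All alternatives here were planned except spots with at least 2000 UMIs and a keratin share of at least 95%, tests chosen only after the result was seen. Over all alternatives, 92 of 94 IL-17 response and glycolysis medians and 1136 of 1162 other list medians were not counted as reversed. The same held for 767 of 768 values of named genes. A list median could count as reversed only if its main interval lay off 0, so sign changes of other medians are not counted. For example, the IL-17 response median for non-lesional skin after over before treatment ranged from -0.12 to 0.09. The IL-17 response median for lesional over non-lesional skin before treatment ranged from 5.34 to 10.14 and the glycolysis median from -1.13 to -0.11. No paired analysis was possible because each group has 1 section, the labels link no sections to a person, and no result comes from a test. In what follows, plaque means pre-treatment lesional over pre-treatment non-lesional, course means post-treatment over pre-treatment lesional, and outside means post-treatment over pre-treatment non-lesional. Except where said, the cause was not tested.

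With TMM scaling the plaque medians were -0.11 for glycolysis, 0.038 for HIF-1 targets outside glycolysis, 0.58 for immediate early and heat shock, 0.35 for melanocyte and 0.38 for sebaceous gland genes, and the course medians -10.25 for IL-17 response, -0.22 for glycolysis and -0.12 for glucose and lactate transport. With median-of-ratios scaling the plaque medians were -0.17 for glycolysis, 0.52 for immediate early and heat shock, 0.29 for melanocyte and 0.32 for sebaceous gland, and the course medians -10.23 for IL-17 response, -0.15 for glycolysis and -0.048 for glucose and lactate transport. Both scalings shift every gene of a comparison by the same amount.

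With every spot thinned to 500 UMIs the plaque medians were 5.34 for IL-17 response, -0.87 for glycolysis, 1.0 for HIF-1 targets, -0.010 for nuclear oxidative phosphorylation, 0.079 for immediate early and heat shock and 0.51 for melanocyte. The course medians were -5.05 for IL-17 response, -0.40 for macrophage and -0.85 for red blood cell, and the outside medians 0.049 for late cornification and 0.71 for lymphatic endothelium. With genes of at least 1 UMI, which adds genes near 0, the plaque medians were 6.64 for IL-17 response and 1.15 for type 17 genes, the course median -9.34 for IL-17 response, and the outside medians 0.35 for type 17 and 1.24 for hair follicle. With at least 50 UMIs per gene the outside median was 0.60 for lymphatic endothelium.

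In spots with at least 2000 UMIs and a keratin share of at least 95%, the plaque median was 0.064 for macrophage, the course medians -0.12 for T cell and -1.29 for red blood cell, and the outside medians 0.74 for lymphatic endothelium and 1.18 for hair follicle. MYL9 stood at -0.41 for lesional over non-lesional after treatment.

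The share of keratin-rich spots moved with its rule by construction. With a keratin share of at least 80% it was 93.9%, 43.3%, 22.5% and 43.3% in the pre-treatment lesional, pre-treatment non-lesional, post-treatment lesional and post-treatment non-lesional sections. The share of keratin-rich spots in percent, post-treatment lesional, was 57.2 with Leiden clusters, and the share of keratin-rich spots in percent, pre-treatment non-lesional, was 75.8 with Leiden clusters and 61.6 with no minimum UMIs per spot. In the pre-treatment lesional section, the rho of IL-17 response thinned to 1000 UMIs was -0.44 with glycolysis and -0.21 with nuclear oxidative phosphorylation, and with no thinning 0.046 with transport and 0.12 with HIF-1 targets.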

Other observations

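Sweat gland transcripts were unevenly spread. The pre-treatment lesional section had 745 UMIs of MUCL1, a small mucin, and 141 of AQP5, a water channel of secretory coils, in its keratin-rich spots although DCD had 0 there. The pre-treatment non-lesional section had 490 and 136, and both post-treatment sections had 0 of each. The keratin-rich sums of the pre-treatment lesional and non-lesional sections held 3484474 and 772926 UMIs, so the rate of both genes was lower in the lesional section. In the pre-treatment non-lesional section the spots with at least 10 DCD UMIs held 6.06% of all UMIs, and 16 of the 17 touched another such spot. MUCL1 and AQP5 in the pre-treatment lesional section were chosen after their values were seen.

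Shallow and deep keratin-rich spots of the pre-treatment lesional section differed. S100A7, S100A8 and S100A9 took 13.65% of the UMIs in the 120 spots with at least 2000 UMIs and 3.78% in the 108 shallower spots. Mitochondrially encoded genes took 1.01% and 3.36%, and fibroblast genes 250 and 5948 CPM. In the pre-treatment non-lesional section the mitochondrially encoded share was 2.95% in 71 deep and 6.02% in 305 shallow spots. These splits were chosen after the data were seen.

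In the pre-treatment lesional section KLRB1, a receptor of type 17 T cells, had 5 UMIs, IL26 had 3, and IL23A and IL23R had 1 each. In the post-treatment lesional section KLRB1 had 2 UMIs, and in the post-treatment non-lesional section IL23A had 1. The pre-treatment lesional section held 3485087 UMIs, against 818510, 600928 and 518806 in the pre-treatment non-lesional, post-treatment lesional and post-treatment non-lesional sections. So few UMIs at such unlike depth show no difference between sections. These genes were chosen after their values were seen.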
